A study of Gallus gallus with 6 samples.

How the data were processed

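RNA was sequenced from 6 samples of chicken primary myoblasts, 3 with ANKRD9 overexpression and 3 with the empty vector pcDNA3.1. Per the labels' protocols, total RNA was purified with RNeasy columns, the molecule was polyadenylated RNA, and libraries were made with an NEBNext Ultra RNA kit, which as named does not mark strand. The labels give more than one amount of input RNA. Per the submitters' processing notes, CASAVA was used and the genome build was GRCg6a, also called galGal6. The aligner, the counting program, its strand setting and all versions are not given in the sources used here.

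The deposited values were FPKM per gene, that is fragments scaled to gene length and to the library total, in one table with 6 columns of libraries, per the file headers, together with each gene's symbol, position, length, biotype and description. Each column was matched to its sample by name, and 0 columns of values were left without a sample. In every library the deposited FPKM times the gene length was a whole multiple of a single step for 100% of the values above 0, within a tolerance of 0.01. Whole reads were recovered in this way, between 16158627 and 26310089 per library. The library total by which the authors divided, as implied by the deposited FPKM, was above the sum of the recovered reads by 1.45%, 1.11% and 1.02% in the ANKRD9 libraries and differed from it by -0.471%, -1.08% and -0.161% in the control libraries, and no source used here explains this. The effect of other scalings is given in the closing section. Recovered reads show how much data lies behind a value, and they are not independent molecules.

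Genes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term and an eBayes fit with a mean trend, after a filter that kept 11685 of 24433 genes with a mean of at least 1 FPKM over the 6 libraries. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and folds in the text are ratios of group means of FPKM. The level of ANKRD9 was also compared by an exact two-sided permutation test. Counts were also made at an absolute log2 fold change of at least 1.

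In all, 32 gene lists were fixed before the data were examined and matched to the table by exact gene symbol. Members without a match were not analysed here. Set tests were run for the 30 lists with at least 5 tested members, leaving out erythroid markers, with 1 tested member, and mitochondrially encoded genes, with none of 13. The set test was camera of limma with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 30 lists, and 12 lists passed. Beside it, camera with an estimated correlation passed 1 list, cell cycle, and fry passed 16. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries rather than from the genes, which by itself raises p. The direction test of fry asks whether a list's genes move one way on balance, and its mixed test, which passed all 30 lists, whether they move in either direction. Neither compares a list with other genes.

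The genes named in the text followed a rule fixed before the data were examined. It takes ANKRD9, the 10 largest rises and 10 largest falls among genes past the threshold that have a symbol and no overlap between the groups' values, every tested member of the IMP synthesis list, and up to 4 members of smallest adjusted p from each other list. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen. Positions are those of the table, on GRCg6a. The table names chromosomes by sequence identifiers, and chromosome names were taken from the genes these share with NCBI's reference table for chicken (assembly GRCg7b), to which 19717 gene identifiers, or 80.7%, matched. No coordinates of that assembly were used. A genome sequence was not used here, so GC content was not checked.

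No library pair of one group agreed within sampling noise. The chi-square per degree of freedom over recovered reads lay between 2.60 and 7.81 within groups and between 24.8 and 40.3 across groups. Over 5118 genes with a mean of at least 1000 reads, the median coefficient of variation between replicates beyond counting error was 3.14%.

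The procedure was tested on simulated data for this comparison, with counts drawn for the real genes at the real library sizes, an assumed dispersion of 0.0015 and 200 genes changed by known folds; 11675 genes passed the filter and were tested. Of 50 genes changed 1.25-fold, 60% were recovered, and of those changed 1.5-fold and 2-fold, 100%. Of 50 genes changed 4-fold, 90% were recovered, because 45 passed the filter on the mean and the other 5, all lowered, did not. A further 20 genes were raised 1.3-fold as a planted list. Calls on unchanged genes made up 5.08% of all calls, and with no change simulated 2 genes were called. Genes were drawn independently with the same dispersion, and far fewer were changed than were called in the real data. The share of false calls therefore need not hold for the real calls.

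The alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, rescaling to TPM, median-of-ratios and quantile scaling, eBayes without a trend or robust, library weights, the repeat number as a block, leaving out each library in turn, voom on recovered reads, other thresholds, the other set tests, and lists without members that stand in more than 1 list. Alternatives added after the data were seen were a mean of at least 20 recovered reads and leaving out both libraries numbered 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.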

Results

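The transcriptomes of chicken primary myoblasts, muscle precursor cells taken from leg muscle, were measured by RNA sequencing of polyadenylated RNA. In 3 libraries the cells overexpressed ANKRD9, and in the other 3 they carried pcDNA3.1, the empty expression vector that served as the control. ANKRD9 is an ankyrin repeat protein that works with Cullin-RING ubiquitin ligases, and the study concerned its role in the metabolism of inosine monophosphate (IMP), the purine nucleotide from which AMP and GMP are made. The deposited FPKM values corresponded to between 16158627 and 26310089 whole reads per library. Of 24433 genes in the table, 11685 had a mean of at least 1 FPKM and were tested. Libraries of one group correlated with each other at a Pearson's r between 0.993 and 0.995 across genes, and libraries of different groups at 0.982 to 0.988. Genes are not independent replicates, so these coefficients only describe the libraries. The first principal component held 58.7% of the variance and separated the groups. Reads on the mitochondrial genome, of which the table lists only tRNA and rRNA genes, took 0.549%, 0.483% and 0.438% of reads in the ANKRD9 libraries and 0.316%, 0.335% and 0.374% in the control libraries. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

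ANKRD9 itself (gene 423469, chromosome 5: 49842186-49843779, minus strand, GRCg6a) was 10.7-fold higher in the overexpressing cells. Its level was 98.7 ± 7.26 FPKM (SD, n = 3) with the ANKRD9 construct and 9.24 ± 0.984 FPKM (SD, n = 3) with the empty vector. The single libraries stood at 90.5, 104 and 101 FPKM in the first group and at 9.46, 8.16 and 10.1 FPKM in the other, resting on 262 to 3393 reads. The log2 fold change was 3.29 ± 0.08 (SE; limma, adjusted p = 5.44e-06), the largest on this scale of any gene past the threshold with a symbol. With a pseudocount of 0.1 it was 3.41, and the small RNA genes MIR6691-1, TRNAM-CAU and MIR1771, on means of 2.33, 1.67 and 2.5 reads, stood at or above it, at 3.47, 3.42 and 3.41. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow. The values do not separate transcripts of the construct from those of the chromosomal gene.

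Besides ANKRD9, the largest rises included genes of cytokines and of a cell death factor. PMAIP1, which encodes a pro-apoptotic protein known as NOXA, rose from 52.0 ± 3.61 to 244 ± 17.3 FPKM (SD, n = 3 each), a 4.69-fold difference. The cytokine gene IL11 rose 4.52-fold, from 11.5 ± 1.85 to 51.7 ± 2.56 FPKM, and the interferon gene IFNKL1 rose 4.41-fold, from 1.98 ± 0.323 to 8.71 ± 1.07 FPKM. PGF, a growth factor of the VEGF family, rose 2.90-fold to 42.0 ± 2.44 FPKM. CSF2, the gene of a granulocyte and macrophage growth factor, rose 3.44-fold to 5.67 ± 1.23 FPKM on a mean of 32.5 reads. On the log2 scale these rises were 2.21 for PMAIP1, 2.09 for IL11, 1.71 for IFNKL1, 1.48 for PGF and 1.32 for CSF2, with adjusted p from 1.17e-05 for PMAIP1 to 5.32e-04 for CSF2 (limma). PMAIP1 lies on chromosome Z: 9445555-9446532, IL11 on chromosome 22: 3602680-3608993, IFNKL1 on chromosome Z: 34282721-34285249, PGF on chromosome 5: 38322843-38327892 and CSF2 on chromosome 13: 17414871-17416684. The other 4 of the 10 largest rises were small RNA genes, MIR181A1, MIR1771, MIR6691-1 and the tRNA gene TRNAM-CAU, a name shared by 14 genes of the table. Of these, MIR181A1 had a mean of 18.3 reads and the others at most 2.5, and the 3 microRNA genes overlap other genes. They are 73 to 110 bases long and the RNA was polyadenylated, so their reads need not come from mature small RNAs.

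The largest falls included the genes of a steroid enzyme, of a muscle growth inhibitor, of a collagen cross-linking enzyme and of a lamin. AKR1D1, which encodes a steroid reductase, was 5.01-fold lower, at 2.51 ± 0.0619 FPKM against 12.6 ± 0.902 FPKM with the empty vector (SD, n = 3 each). MSTN, the gene of the muscle growth inhibitor myostatin, was 2.86-fold lower, at 4.45 ± 0.836 against 12.7 ± 1.12 FPKM. LOX, which encodes the collagen cross-linking enzyme lysyl oxidase, was 2.75-fold lower, at 6.69 ± 1.38 against 18.4 ± 3.00 FPKM. The chemokine receptor gene CCR8L was 2.83-fold lower, the lamin gene LMNB2 2.40-fold, the matrix gene MXRA5 2.46-fold and SOD3, the gene of extracellular superoxide dismutase, 3.04-fold. The log2 fold changes were -1.95 for AKR1D1, -1.34 for MSTN and for LOX, -1.22 for CCR8L and for LMNB2, -1.19 for MXRA5 and -1.15 for SOD3, with adjusted p from 1.17e-05 for AKR1D1 to 6.43e-04 for LOX (limma). AKR1D1 lies on chromosome 1: 56550520-56584579, MSTN on chromosome 7: 252348-257840 and LOX on chromosome Z: 81200691-81207932. MSTN overlaps C2orf88 on the opposite strand, and the counting strand is not given, so reads of the pair are not told apart. The remaining 3 of the 10 largest falls, the microRNA genes MIR6572, MIR7474 and MIR1579, rested on means of 6, 3.33 and 1.5 reads. Their reads, too, need not come from mature small RNAs. MIR6572 passed narrowly (adjusted p = 0.0482, limma) and lost its call in 4 of the 6 fits that left out a single library (adjusted p between 0.0601 and 0.125), while MIR7474 lost it without pcDNA3.1 replicate 2 (adjusted p = 0.0578) and MIR1579 without ANKRD9 replicate 2 (adjusted p = 0.0536). With a pseudocount of 0.1 the adjusted p of MIR6572 and MIR7474 was 0.112 and 0.0734. MIR1579, MIR6691-1 and TRNAM-CAU dropped under the filter on low values in some of these fits.

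**Figure D1:**
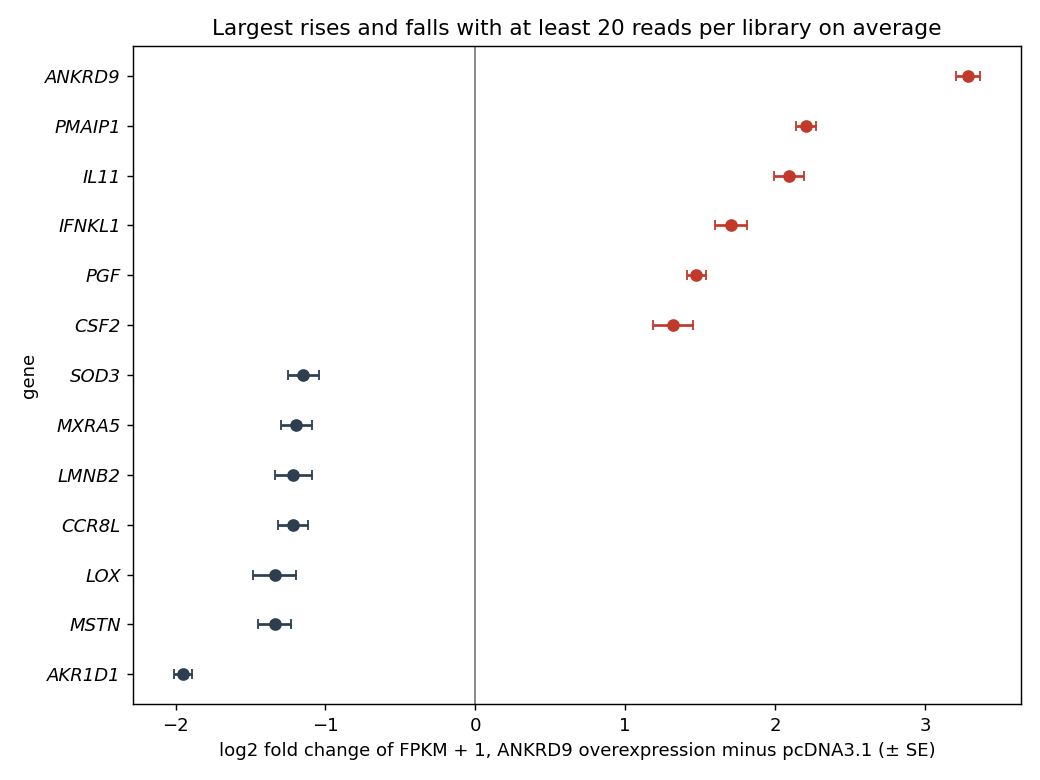
Log2 fold change of FPKM + 1 between ANKRD9 overexpression and pcDNA3.1 (horizontal axis) for the genes among the 10 largest rises and 10 largest falls that had at least 20 reads per library on average. Points are the fitted values and bars their SE from 3 libraries per group; ANKRD9 stands at 3.29 and AKR1D1 at -1.95.

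Across the transcriptome, 1900 genes were higher and 2310 lower with ANKRD9 at an adjusted p under 0.05 (limma), 36.0% of those tested. The median difference among these genes was 1.22-fold. A log2 difference of at least 1 was reached by 31 of the higher and 16 of the lower genes. The 3 values of one group lay wholly above the 3 of the other for 5917 genes, or 50.6%, where chance gives 10%. Without ANKRD9 replicate 2 the number of higher genes was 1257. The counts at a log2 difference of at least 1 depended on the treatment of low values, as 71 higher and 31 lower genes passed with a pseudocount of 0.1, and 19 and 9 among genes with a mean of at least 5 FPKM.

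IMP synthesis is the pathway that the study asked about. Of its 11 members tested, 6 were lower, none was higher, and 5 did not pass, and the counts were unaltered when adjusted over the list alone. The genes that fell included those for making phosphoribosyl pyrophosphate, and PPAT, GART and PAICS for steps that follow it. PRPS1 and PRPS2, which encode the synthetases of phosphoribosyl pyrophosphate, fell by 0.38 ± 0.04 and 0.73 ± 0.08 on the log2 scale (SE), from 97.1 ± 3.36 to 74.3 ± 0.436 FPKM and from 4.54 ± 0.366 to 2.34 ± 0.217 FPKM (SD, n = 3 each). PPAT, which encodes the amidotransferase of the committed step, fell by 0.42 ± 0.04, from 16.3 ± 0.487 to 11.9 ± 0.200 FPKM. GART fell by 0.34 ± 0.05 to 8.13 ± 0.231 FPKM and PAICS by 0.37 ± 0.04 to 32.1 ± 0.986 FPKM. IMPDH2, the dehydrogenase that takes IMP toward GMP, was lower by 0.13 ± 0.04 on the log2 scale, at 108 ± 4.45 against 118 ± 1.55 FPKM. The adjusted p ran from 5.04e-04 for PPAT to 0.0469 for IMPDH2 (limma).

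The remaining 5 members did not pass the test. ADSL, for adenylosuccinate lyase, stood at 46.2 ± 2.04 FPKM with ANKRD9 and 45.8 ± 1.02 FPKM with the vector, and ATIC, for the enzyme that closes the IMP ring, at 49.6 ± 0.865 and 52.0 ± 0.772 FPKM. GMPS stood at 24.3 ± 1.82 and 25.2 ± 1.85 FPKM, ADSSL1 at 8.34 ± 0.321 and 8.85 ± 0.358 FPKM, and ADSS at 48.7 ± 2.61 and 47.2 ± 2.99 FPKM, with adjusted p between 0.184 and 0.867. As a set the list was lower than other genes (camera, adjusted p = 0.00536 over 30 lists). With an estimated correlation, which at -0.0495 was below the preset 0.01, the adjusted p was 0.154 (camera). IMPDH2 lost its call when any single library other than ANKRD9 replicate 1 was left out, with adjusted p between 0.0764 and 0.163, and also under median-of-ratios or quantile scaling, without a filter, and with an eBayes fit that was robust or had no trend. PPAT and PAICS overlap each other on opposite strands, PRPS2 overlaps TLR7 and GART overlaps an antisense gene. The listed members PFAS and IMPDH1 were not analysed here.

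**Figure D2:**
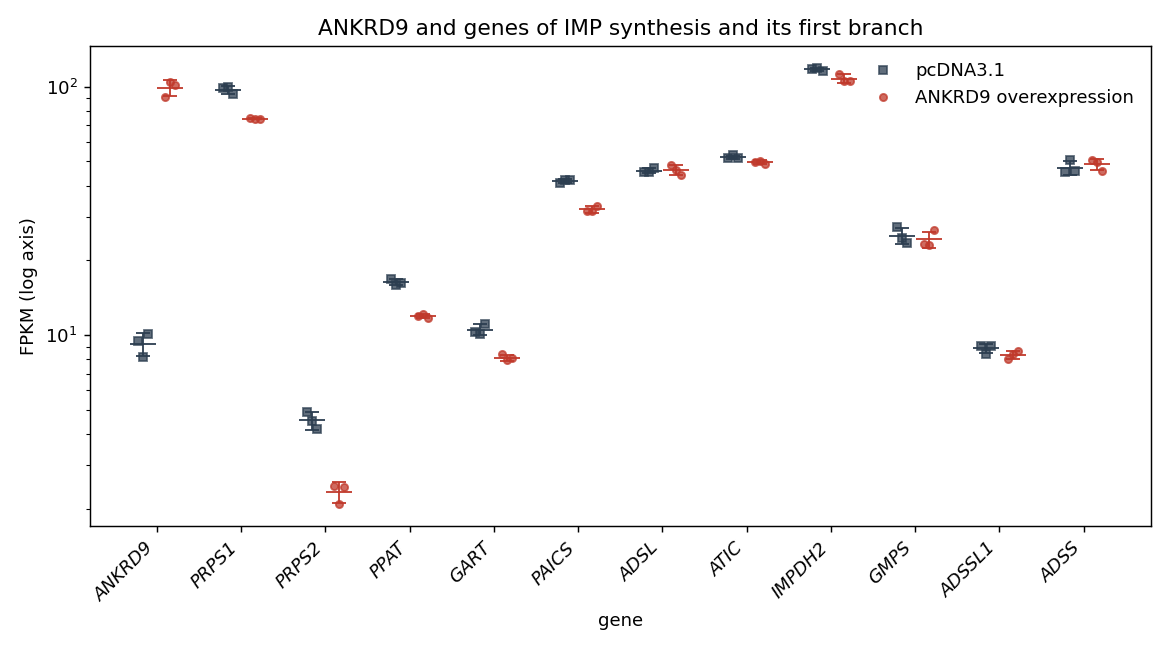
FPKM (log axis) of ANKRD9 and the 11 tested genes of IMP synthesis and the steps that follow IMP, with one point per library, 3 per group, and the group mean with SD. ANKRD9 is higher by 10.7-fold with overexpression, and PRPS1, PRPS2, PPAT, GART and PAICS lie lower in all 3 ANKRD9 libraries than in any pcDNA3.1 library.

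In other nucleotide pathways the genes that fell included those of enzymes that make DNA precursors. Of these, RRM1, RRM2 and TK1 are also members of the cell cycle list given below, so their falls are not separate from those of that list. Of 39 purine salvage, interconversion and breakdown genes, 9 were lower and 6 higher. The ribonucleotide reductase genes RRM1 and RRM2 fell 1.58-fold and 1.42-fold, to 27.0 ± 1.27 and 65.1 ± 0.930 FPKM (SD, n = 3), whereas the phosphodiesterase gene PDE4B and the nucleotidase gene ENTPD4 each rose 1.35-fold. Of 17 pyrimidine synthesis genes, 8 were lower and 2 higher. DCTD fell 1.83-fold, DUT 1.55-fold, TK1 1.27-fold and CMPK1 1.22-fold. Neither list passed as a set (camera, adjusted p = 0.377 and 0.0748), although the pyrimidine list passed without ANKRD9 replicate 2 (adjusted p = 0.0474) and without pcDNA3.1 replicate 3 (adjusted p = 0.0360). By fry, which does not compare a list with other genes, both moved downward on balance (adjusted p = 0.00166 and 0.00219).

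One-carbon and serine metabolism, which supplies carbon for purine and thymidylate synthesis, had 9 of 18 members lower and 1 higher, and 11 lower when adjusted over the list alone. PSAT1 of serine synthesis fell 1.50-fold, and the folate enzymes MTHFD1 and MTHFD1L fell 1.35-fold and 1.33-fold. The thymidylate synthase gene TYMS, also a member of the pyrimidine and cell cycle lists, fell 1.66-fold. The one-carbon list was lower as a set (camera, adjusted p = 0.00892), and with an estimated correlation the adjusted p was 0.154. In the pentose phosphate pathway, the source of ribose phosphate, 3 of 12 genes were lower and 2 higher, and the list did not pass (camera, adjusted p = 0.860). DERA fell 1.33-fold, RPIA 1.21-fold and RBKS 1.18-fold, and TALDO1 rose 1.16-fold. The calls of TALDO1 and RBKS each depended on single libraries, TALDO1 on ANKRD9 replicates 1 and 2 (adjusted p = 0.0532 and 0.0510 without them) and RBKS on pcDNA3.1 replicate 3 (adjusted p = 0.0548 without it).

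Cell cycle genes fell together. Of 104 tested members, 92 were lower, none was higher and 12 did not pass, and 94 were lower when adjusted over the list alone. The cytokinesis gene ANLN fell 1.78-fold from 55.9 ± 1.68 to 31.4 ± 0.836 FPKM (SD, n = 3 each), the mitotic kinase gene PLK1 1.73-fold from 44.6 ± 1.42 to 25.9 ± 0.325 FPKM, the condensin gene SMC2 1.85-fold to 22.5 ± 0.665 FPKM and DLGAP5 1.82-fold to 8.29 ± 0.467 FPKM. The median log2 fold change of the list was -0.47 (camera, adjusted p = 3.98e-29), and it alone passed narrowly with an estimated correlation (adjusted p = 0.0499). Among 28 targets of p53, 10 were higher and 3 lower. After PMAIP1, the cyclin-dependent kinase inhibitor gene CDKN1A rose 1.60-fold from 282 ± 12.6 to 451 ± 4.76 FPKM, PLK2 1.44-fold and SESN1 1.37-fold. The p53 list was higher as a set (camera, adjusted p = 0.0158), and with an estimated correlation the adjusted p was 0.154. Of 27 immediate early genes, 13 were higher and 2 lower. ATF3 rose 1.68-fold, KLF4 1.60-fold and DUSP1 1.41-fold, while EGR1 fell 1.66-fold from 65.5 ± 3.67 to 39.4 ± 2.41 FPKM. This set was higher (camera, adjusted p = 3.81e-04), and the adjusted p was 0.154 with an estimated correlation.

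Interferon response genes were mostly higher, with 36 of 62 members up and 4 down. HELZ2 rose 2.49-fold from 61.2 ± 8.45 to 153 ± 15.4 FPKM (SD, n = 3 each). The chemokine gene CCL19 rose 2.15-fold, the viral RNA sensor gene IFIH1 1.91-fold from 108 ± 3.37 to 205 ± 11.4 FPKM, and the antiviral gene RSAD2 1.71-fold. The set was higher (camera, adjusted p = 1.66e-08), and with an estimated correlation the adjusted p was 0.154. Inflammatory genes and targets of NF-kB had 26 of 44 members higher and 4 lower, or 30 higher when adjusted over the list alone. The chemokine gene CCL4, one of 2 genes of that name in the table, rose 1.93-fold from 2127 ± 109 to 4113 ± 92.4 FPKM. The matrix metalloproteinase gene MMP9 rose 1.74-fold, the NF-kB inhibitor gene TNFAIP3 1.66-fold and the nitric oxide synthase gene NOS2 1.59-fold. The set was higher (camera, adjusted p = 1.01e-08), and with an estimated correlation the adjusted p was 0.179.

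Of 17 leukocyte markers, 5 were higher, none was lower and 12 did not pass. When adjusted over the list alone, 3 were higher. NCF1 rose 1.72-fold from 24.3 ± 0.518 to 41.7 ± 2.00 FPKM, the transcription factor gene SPI1 1.50-fold, CD3E 2.41-fold from 1.51 ± 0.599 to 3.64 ± 0.658 FPKM and RAC2 1.48-fold. The leukocyte set passed narrowly (camera, adjusted p = 0.0422). It did not pass with an estimated correlation (adjusted p = 0.539), without ANKRD9 replicate 1 (adjusted p = 0.124), without pcDNA3.1 replicate 1 (adjusted p = 0.0720), without pcDNA3.1 replicate 2 (adjusted p = 0.0512), without both libraries numbered 1 (adjusted p = 0.185), with library weights (adjusted p = 0.116), without a filter (adjusted p = 0.0953) or with a mean of at least 5 FPKM (adjusted p = 0.0671), and the call of RAC2 was lost without any one of 5 libraries, the exception being pcDNA3.1 replicate 2 (adjusted p between 0.0611 and 0.122).

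Genes of the extracellular matrix and of fibroblasts were mostly lower, with 27 of 39 down and 6 up. The collagen genes COL3A1 and COL1A2 fell 2.02-fold and 1.59-fold, from 173 ± 9.87 to 86.0 ± 4.52 FPKM and from 311 ± 19.5 to 195 ± 4.46 FPKM (SD, n = 3 each). MFAP5 of the microfibrils fell 2.04-fold and FBLN2 1.84-fold. The set was lower (camera, adjusted p = 2.06e-06), and with an estimated correlation the adjusted p was 0.386. Cholesterol and fatty acid synthesis genes were lower in 23 of 33 cases and higher in 1, with 28 lower when adjusted over the list alone. The desaturase gene FADS2 fell 1.52-fold, the sterol enzyme gene MSMO1 fell 1.28-fold, and INSIG1, a sensor of sterols, fell 1.31-fold. The set was lower (camera, adjusted p = 3.76e-07), and the adjusted p was 0.154 with an estimated correlation. Of 66 ribosomal protein genes, 38 were lower, none was higher and 28 did not pass. RPL8, RPSA and RPL3 each fell by 0.33 on the log2 scale and RPLP0 by 0.28. That set was lower by camera (adjusted p = 9.23e-09), but with an estimated correlation the adjusted p was 0.681, and fry gave an adjusted p of 0.0596. Ribosome biogenesis genes had 11 of 41 lower and 3 higher and did not pass as a set (camera, adjusted p = 0.377). NOC4L, RRP1B and WDR43 fell 1.38-fold, 1.22-fold and 1.17-fold, and TAF1D rose 1.17-fold, a call lost without both libraries numbered 1 (adjusted p = 0.0568).

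**Figure D3:**
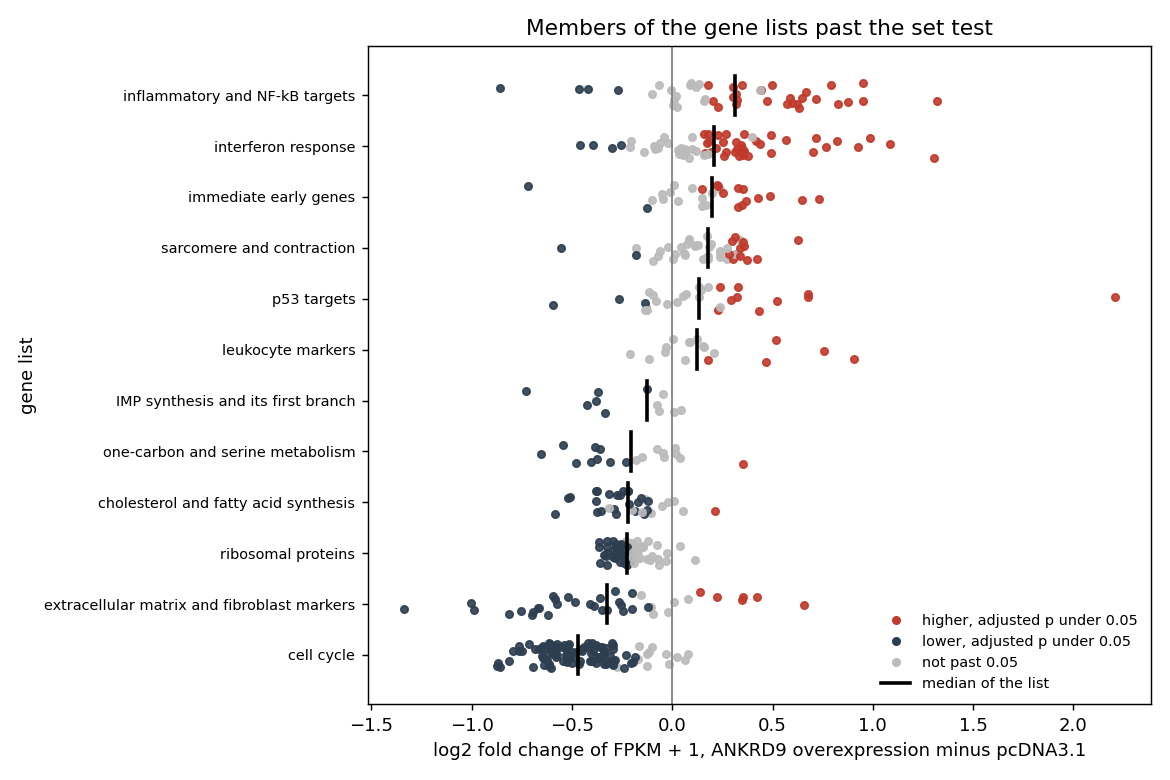
Log2 fold change of FPKM + 1 between ANKRD9 overexpression and pcDNA3.1 (horizontal axis) for each tested member of the 12 gene lists with a camera adjusted p under 0.05. Each point is a gene, coloured by whether it was higher, lower or not past an adjusted p of 0.05, and the black bar is the median of the list. The cell cycle list has the lowest median, at -0.47.

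Muscle genes moved in different directions. Of 31 myogenic regulators, 8 were higher and 6 lower. Besides MSTN, the myogenic transcription factor gene MYOD1 fell 1.72-fold from 199 ± 6.77 to 116 ± 11.3 FPKM (SD, n = 3 each), whereas FST, the gene of the myostatin antagonist follistatin, rose 1.47-fold and the transcription factor gene MYF6 1.23-fold. The list did not pass as a set (camera, adjusted p = 0.702), and its median log2 fold change of 0.07 and mean of -0.02 differed in sign. Of 44 sarcomere and contraction genes, 12 were higher and 2 lower. The troponin gene TNNT1 rose 1.55-fold from 78.2 ± 11.0 to 121 ± 11.1 FPKM, MYOM3 1.26-fold and LMOD2 1.23-fold, and the calcium channel subunit gene CACNG1 fell 1.52-fold. That set was higher (camera, adjusted p = 0.00197) but did not pass with an estimated correlation (adjusted p = 0.740), by fry (adjusted p = 0.153) or without both libraries numbered 1, a test chosen after the data were seen (adjusted p = 0.108).

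Lists of energy metabolism held single genes that changed, and none of the 4 passed camera in the fit reported here, though 2 passed by another test or setting. Of 19 glycolysis genes, 6 were lower and 3 higher, and the list did not pass camera (adjusted p = 0.581), whereas fry gave a downward direction on balance (adjusted p = 0.0420). ENO1 fell 1.20-fold from 1296 ± 67.5 to 1082 ± 5.84 FPKM (SD, n = 3 each), the lactate transporter gene SLC16A1 1.21-fold and GPI 1.15-fold, and ENO2 rose 1.30-fold. The call of GPI was lost without both libraries numbered 1 (adjusted p = 0.0514). Nuclear genes of oxidative phosphorylation had 10 of 62 lower and 1 higher, or 5 lower and none higher when adjusted over the list alone. COX5A fell 1.63-fold, NDUFB6 1.38-fold, SDHD 1.37-fold and UQCRFS1 1.28-fold. This list did not pass (camera, adjusted p = 0.124), but it passed without pcDNA3.1 replicate 1 (adjusted p = 2.28e-04), without ANKRD9 replicate 1 (adjusted p = 0.0465), without both libraries numbered 1 (adjusted p = 1.95e-05), on the TPM scale (adjusted p = 0.0302), without a filter (adjusted p = 0.0252) and with library weights (adjusted p = 0.0210). Those passes all used the preset correlation. With an estimated correlation of 0.563 the adjusted p was 0.912 (camera), and fry gave 0.365. The mitochondrially encoded messenger RNAs were not analysed here. Among 31 genes of AMPK, insulin and energy sensing, 5 were lower and 2 higher. IGFBP4 fell 1.81-fold from 119 ± 1.58 to 65.5 ± 2.26 FPKM, IGFBP2 1.41-fold and PDK3 1.25-fold, and PPARD rose 1.31-fold. Of 29 hypoxia response genes, 9 were higher and 7 lower. Besides the fall of LOX, PFKFB3, for a regulator of glycolysis, rose 1.85-fold, ANGPTL4 rose 1.35-fold and P4HA1 fell 1.36-fold. Neither of these lists passed (camera, adjusted p = 0.992 and 0.965). Their signs were mixed, as the energy sensing list had a median log2 fold change of 0.01 and a mean of -0.02, and the hypoxia list had a median of -0.05 and a mean of -0.03 with an upward direction by camera and fry.

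Stress and protein turnover lists did not pass camera. Of 40 genes of the amino acid stress and unfolded protein response, 8 were lower and 6 higher (camera, adjusted p = 0.992), with a median log2 fold change of 0.00 and a mean of -0.01. ATF3 was among the higher genes, as was CHAC1 at 1.37-fold, and the amino acid transporter gene SLC7A5 fell 1.48-fold. Of 27 heat shock genes, 7 were higher and 6 lower (camera, adjusted p = 0.830), and fry gave a downward direction on balance (adjusted p = 0.00107). HSP90AA1 fell 1.36-fold from 475 ± 7.09 to 350 ± 10.2 FPKM (SD, n = 3 each) and HSPB11 1.47-fold, while HSPB9 rose 1.55-fold and DNAJA1 1.20-fold. Of 25 autophagy genes, 7 were higher and 4 lower (camera, adjusted p = 0.180), and fry gave an upward direction (adjusted p = 7.00e-04). The autophagy receptor gene SQSTM1 rose 1.52-fold from 122 ± 1.75 to 185 ± 6.87 FPKM, ULK1 1.45-fold, GABARAPL2 1.28-fold and OPTN 1.25-fold. Of 24 Cullin-RING ligase subunits, the complexes with which ANKRD9 works, 7 were lower and 2 higher (camera, adjusted p = 0.827). SKP1, COPS2, COPS8 and CUL4B fell by 0.27, 0.22, 0.21 and 0.16 on the log2 scale, and the call of CUL4B was lost without both libraries numbered 1 (adjusted p = 0.0672).

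Markers of other cell types, leukocytes and fibroblasts aside, did not pass camera in the fit reported here. Smooth muscle markers had 4 of 13 lower and 2 higher, with ACTA2, ACTG2 and LMOD1 lower by 1.29-fold, 1.29-fold and 1.52-fold and DES higher by 1.26-fold (camera, adjusted p = 0.581). Adipocyte markers had 9 of 18 lower and 6 higher (camera, adjusted p = 0.810). CIDEC rose 1.97-fold and PPARG 1.40-fold, and ZNF423 and LPL fell 1.44-fold and 1.22-fold. Endothelial markers had 3 of 12 higher and 2 lower (camera, adjusted p = 0.827), with CLDN5 higher by 1.50-fold, PECAM1 by 1.29-fold, and TEK and EGFL7 lower by 1.88-fold and 1.35-fold. Its median and mean were above 0, whereas fry gave a downward direction (adjusted p = 0.878). Chondrocyte and bone markers had 3 of 7 higher and 1 lower, with RUNX2 up 1.51-fold, BGLAP 1.30-fold, COL9A3 1.75-fold and ALPL down 1.44-fold (camera, adjusted p = 0.0848, and 0.0384 on the TPM scale), and fry gave an upward direction (adjusted p = 0.0442). The call of COL9A3 was lost without both libraries numbered 1 (adjusted p = 0.0857). The call of ALPL was lost without any one of 5 libraries, the exception being pcDNA3.1 replicate 1 (adjusted p between 0.0630 and 0.106). Of 6 glial and neural markers, PMP22 was 1.14-fold higher and FABP7 1.17-fold lower (camera, adjusted p = 0.860), the call of PMP22 being lost without any one library except ANKRD9 replicate 2 (adjusted p between 0.0706 and 0.138) and that of FABP7 without ANKRD9 replicate 1 (adjusted p = 0.0573). Of the erythroid markers only TFRC, the transferrin receptor gene, was tested, and it fell 1.67-fold from 22.9 ± 2.48 to 13.8 ± 1.67 FPKM (SD, n = 3 each).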

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

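The tests with at least 20 reads and without both libraries numbered 1 were chosen after the data were seen. ANKRD9 stayed higher and past the threshold under every alternative run for it, with log2 fold changes from 3.21 to 3.41. Over the 19 of 25 alternatives that were run for named genes, 124 of the 141 kept their direction and their side of the threshold wherever they were tested. No called gene of the transcriptome was called in the opposite direction under any alternative, and voom called 3967 of the 4210 genes in the same direction.

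The counts of higher and lower genes, 1900 and 2310, were 970 and 1225 at an adjusted p under 0.01 and 31 and 16 at an absolute log2 fold change of at least 1, both by construction. Leaving out single libraries gave 1257 to 1755 higher and 1574 to 2148 lower genes, the lowest without ANKRD9 replicate 2, with fewer samples in each fit. The higher share of calls was 45.1% as reported, 39.5% on the TPM scale and 52.0% with voom. The counts of 31 and 16 at that fold change became 71 and 31 with a pseudocount of 0.1, 19 and 9 with a mean of at least 5 FPKM, 20 and 10 with a mean of at least 20 reads and 81 and 33 with voom on recovered reads, and the lower count became 25 on the TPM scale. Fewer genes tested accounts for the filters. A smaller pseudocount enlarges the log2 fold changes of low genes by arithmetic. For voom and the TPM scale the cause was not tested. Named genes such as MIR6691-1, TRNAM-CAU and MIR1579 rested on means of 2.33, 1.67 and 1.5 reads, so counting error limits how well their folds are known.

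Of the 30 gene lists, 12 passed as reported and 1 with an estimated correlation. Over the 21 alternatives run for lists, 4 lists kept their direction and side of the threshold throughout, and 8 lists, none of which passed as reported, reversed under at least 1. The IMP synthesis list had an adjusted p of 0.154 with an estimated correlation and 0.00422 to 0.0107 when single libraries were left out. The estimate takes the place of the preset value of 0.01. It lay below that value for IMP synthesis (-0.0495), one-carbon metabolism (-0.0188), p53 targets (-0.0123) and immediate early genes (-0.00778), which also lost their calls. For these lists a higher correlation among their genes is argued against as the reason. For the other lists that lost their calls it was higher, from 0.0633 for interferon response to 0.820 for ribosomal proteins. The estimated setting also takes its degrees of freedom from the libraries and not from the genes, which raises p even without correlation. How much of each loss this accounts for was not tested. Camera has no robust setting, so that alternative was not run for lists, and voom was run for gene counts alone.

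Reversals of direction were seen only in results that did not pass as reported. ADSL had a log2 fold change of -0.0105 on the TPM scale, -0.0190 to 0.0434 when single libraries were left out and -0.0269 without both libraries numbered 1. Without that pair, GMPS had 0.0342 and ADSS -0.0123, and GMPS ranged from -0.106 to 0.00780 when single libraries were left out. Adjusted p in reversed lists was 0.947 for hypoxia without a filter and 0.980 on the TPM scale, 0.835, 0.924, 0.602, 0.983 and 0.996 for amino acid stress with a mean of at least 5 FPKM, median-of-ratios, quantile, no trend and at least 20 reads, 0.816, 0.939 and 0.111 for energy sensing with at least 5 FPKM, TPM and fry, 0.878 for endothelial markers by fry, 0.800 for adipocyte markers without shared members and 0.851 for myogenic regulators without both libraries numbered 1. When single libraries were left out, adjusted p ranged from 0.711 to 0.957 for the pentose phosphate list, 0.838 to 0.963 for amino acid stress, 0.590 to 0.936 for Cullin-RING ligases, 0.888 to 0.960 for hypoxia and 0.783 to 0.973 for energy sensing.

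The labels do not say whether the repeat numbers pair the libraries. The deviations of same-numbered libraries correlated between -0.196 and 0.0336. These values show no shared deviation, but they cannot settle how the libraries were prepared. With the repeat number as a block, 1420 genes were higher and 1693 lower, the number of lists called was 12 as before, and ANKRD9 kept a log2 fold change of 3.29. Of the called named genes, MIR6572, IMPDH2, RAC2, PMP22 and CUL4B did not pass with the block, with adjusted p from 0.0569 for CUL4B to 0.101 for IMPDH2.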

Other observations

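The genes of this paragraph and the next were chosen after their values were seen. Genes of some secreted factors and of a receptor also rose with ANKRD9, all but IL8L2 from outside the fixed lists. They were picked because they rose, and secreted factors were not tested as a set. BDKRB1, a bradykinin receptor gene, rose 2.35-fold from 72.1 ± 2.73 to 170 ± 8.78 FPKM (SD, n = 3 each; limma, adjusted p = 4.77e-05). TNFRSF11B and TNFSF11, which encode the osteoprotegerin and RANKL pair of bone biology, rose 1.85-fold and 1.72-fold, to 30.9 ± 0.0890 and 10.2 ± 0.357 FPKM. GDF15, a stress-induced growth factor gene, rose 1.73-fold to 162 ± 7.42 FPKM, HBEGF 1.74-fold to 62.8 ± 0.959 FPKM and the activin subunit gene INHBB 3.30-fold to 1.79 ± 0.199 FPKM. IL8L2, an interleukin gene already counted in the inflammatory list, stood at 4679 ± 266 FPKM with the empty vector and rose 1.27-fold.

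Among genes of developmental transcription factors, some rose and others fell, and no fixed list of them was tested. MSX2 rose 1.92-fold from 14.9 ± 0.893 to 28.6 ± 1.82 FPKM, PRDM8 2.69-fold, MITF 1.81-fold, HEY1 1.75-fold and MEOX2 1.62-fold, while PITX3 fell by 0.82 and DBX1 by 0.77 on the log2 scale, to 9.14 ± 0.774 and 29.4 ± 2.66 FPKM (SD, n = 3 each; adjusted p at most 3.54e-04, limma). Among 299 long noncoding RNA genes 48 were higher and 20 lower. Over all 11685 tested genes 1900 were higher and 2310 lower, so the higher share was near that of all genes and the lower share was smaller. Of 123 protein families with at least 8 tested members, the family labelled kinesin had 13 of 20 lower, 4 of these in the cell cycle list, and none higher (camera, adjusted p = 6.90e-04). That label leaves out some kinesin genes of the cell cycle list, such as KIF20A. The serpins had 8 of 10 lower (camera, adjusted p = 0.00622) and the EGF_CA family 8 of 17 lower, 3 of these in the fixed lists (camera, adjusted p = 0.00622). None of the 123 families passed camera with an estimated correlation (adjusted p = 0.994 for each of these 3). That setting therefore does not tell these families from the others. The homeobox family had 8 of 35 higher and 7 lower and did not pass (camera, adjusted p = 0.625). ODF3L15 stood at 4.06, 17.3 and 23.6 FPKM in ANKRD9 replicates 1, 2 and 3 and at 3.77, 4.03 and 4.48 FPKM in the control libraries, and did not pass (adjusted p = 0.0734).

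In what follows, the tests of splits, of leukocytes, of mitochondrial reads on nuclear genes and of rRNA without single libraries were chosen only after the results they bear on were seen. The real split of the 6 libraries called 4210 genes, and the highest of the other splits called 1. It was the 1 split of 10 with as many, and 10 splits are too few for a share under 0.05.

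The rise of interferon and inflammatory genes was set against technical explanations. Expression level or gene length as the whole cause is argued against, since the medians of both lists lay at percentile 100 of 10000 random lists matched on both. More leukocytes in the ANKRD9 cultures may account for part of the rise and cannot be told apart from a response of the myoblasts. The median of the 15 of 17 tested leukocyte genes that stand in neither list was 0.12 on the log2 scale with a 95% bootstrap interval from 0.00 to 0.47, and all 106 tested interferon and inflammatory genes had a median of 0.24, inside that interval. The interval was drawn over the 15 genes and not over libraries, so it measures only the spread between genes. Its upper bound is the value of RAC2, whose call depended on single libraries. NCF1, the most abundant of the leukocyte genes, rose to 41.7 FPKM, whereas the macrophage genes C1QA, C1QB and C1QC, at 5.14, 4.20 and 3.76 FPKM with ANKRD9 and 4.60, 4.32 and 4.12 FPKM with the vector, did not pass, and a difference in the plasmid dose between groups was not tested.

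The lower level of IMP synthesis genes was set against expression level and gene length. The median of the list was -0.127 on the log2 scale. It lay at percentile 3.68 among matched random lists, inside their central range of -0.141 to 0.136. By that test expression level and gene length are not excluded as the cause. The range lay on both sides of 0, so matched lists showed no general fall. A median of this size can arise by chance in a list of 11 genes, and 5 of the 11 members did not pass. Cell cycle genes were lower in the same comparison, and neither a link between both lists nor an action of ANKRD9 on the pathway was tested.

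Mitochondrial rRNA and 2 nuclear genes that overlap each other on the same strand rose together. The rRNA took 0.263%, 0.235% and 0.216% of reads in the ANKRD9 libraries and 0.151%, 0.153% and 0.183% in the control libraries. Other mitochondrial reads, on tRNA genes, also took a larger share in every ANKRD9 library than in any control library. The 12S rRNA rose 1.50-fold to 1130 ± 66.7 FPKM and the 16S rRNA 1.39-fold to 769 ± 99.9 FPKM, and LOC112530942, described as similar to a subunit of mitochondrial NADH dehydrogenase, rose 1.75-fold from 782 ± 96.8 to 1369 ± 220 FPKM (SD, n = 3 each), with LOC101750014, described as uncharacterized, rising 1.51-fold, and no sequences were compared. In single libraries LOC112530942 departed from the summed rRNA by up to 0.216 on the log2 scale and LOC101750014 by up to 0.140, and 12.7% of 1889 other higher genes came as close as the first, so reads of mitochondrial RNA counted on the nuclear genes cannot be told apart from a rise of the genes themselves. A single library as the cause is argued against, since both rRNA stayed higher and past the threshold when any one of the 6 libraries was left out, with log2 fold changes of at least 0.37 and adjusted p of at most 0.0409 (limma). Whether the rise reflects the share of mitochondrial RNA carried through polyadenylated selection or the cells themselves stays open, and no biological explanation was tested.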
